A study of Rattus norvegicus with 9 samples.

How the data were processed

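RNA was taken from tissue that had grown inside nerve conduits in rats, and each of 9 libraries stands for 1 conduit group and 1 replicate number: Hollow, AFMC and AFMC-AA-SP, with 3 libraries each. Per the labels, transcripts with poly(A) tails were captured, the libraries keep the strand by the dUTP method, inserts measured 250 to 350 bp, and both ends were read over 150 bp. Per the file headers, the deposited gene table holds counts and FPKM for 21486 genes, of which 19453 are annotated as protein coding and 2020 as lncRNA. The deposited counts are whole numbers and were not scaled. The deposited FPKM values are the counts divided by 1 length per gene and by the library's total, since the length they imply was the same in all 9 libraries. The aligner, the counting program, the annotation release and the genome build are not given in the sources used here. Coordinates are printed as the deposited table lists them, as gene spans. The poly(A) capture leaves transcripts without a tail largely unmeasured, and no molecular identifiers were used, so counts are reads and not molecules.

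Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the groups, which left 15659. TMM factors scaled the libraries, and a quasi-likelihood model with a term per conduit group was fitted to all 9 libraries. The common biological coefficient of variation was 0.197. AFMC was compared with Hollow, AFMC-AA-SP with AFMC, and AFMC-AA-SP with Hollow. The series text names the comparisons of AFMC with Hollow and of AFMC-AA-SP with AFMC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with no minimum fold. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values use the TMM-scaled library totals and are printed as group mean ± SD. Library totals ran from 18314489 to 26074134 counts. The labels do not say which animals or how many the libraries came from, so each p-value measures only the spread between these libraries. An exact permutation test of a single value on 3 against 3 libraries cannot give a p below 0.1.

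Groups of genes were tested with camera from limma 3.58.1, at its preset correlation between genes of 0.01, over 40 lists written before the data were examined. The lists cover the cells of nerve, immune cells, connective and vascular tissue, fat, muscle and blood, and pathways that fit a conduit, spermidine or ascorbic acid. They hold 861 members, of which 763 were tested and 53 were not analysed here. A list was called at an adjusted p under 0.05 over the 40 lists. Camera compares a list with all other genes. The same test was run with a correlation estimated from the data, and fry tested whether a list moved on balance in 1 direction. Counts within a list are also given adjusted over the list alone. A list's score in a library is the mean log2 CPM of its members relative to all 9 libraries, and its difference between groups is given with its standard error. The study's own short sheets of genes were tested apart. They were chosen by the study on these samples, so they are not independent evidence. The guidance receptors have their own sheet, and the other groups are sections of another sheet, each called a sheet here. On the sheet with sections, 396 of 396 values equal the FPKM table within 1e-04. The guidance receptor sheet was not compared with that table. Annotation terms with 10 to 300 tested genes were tested with Fisher's exact test, one-sided, on called genes.

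The named genes follow a rule fixed before the data were examined. For each comparison and direction it takes the called genes of largest change, or, where fewer than 3 are called, the 3 genes of smallest p that have a symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups. It adds 2 members of each called list, 18 genes set in advance and the 2 members of smallest p from each of the study's sheets. A symbol held by several genes was read as the gene with the most counts. Genes or libraries named outside the rule are described as chosen after their values were seen.

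The steps were tested on simulated counts with the gene means, gene spreads and library totals of these data. They held 200 changed genes, all with a mean above 5 CPM. Genes varied independently there, with no library standing apart and no trend with gene length. The shares recovered therefore need not hold for the real libraries. In the comparison of AFMC with Hollow, edgeR recovered 8%, 74%, 98% and 98% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 10 false calls. DESeq2 recovered 36%, 86%, 100% and 98%, with 48 false calls. Alternatives fixed before the data were examined were RLE and upper-quartile factors, no filter on low counts, a filter at 1 CPM in 3 libraries, only the 2 groups compared, a minimum log2 fold change of 1, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, the other set tests, and leaving out each library in turn. Alternatives chosen after seeing the data were an offset per library that follows gene length, limma voom with a weight per library, the length offset without AFMC replicate 3, and camera over the annotation terms, with all libraries and with each left out in turn. The labels do not say whether the numbers 1 to 3 mark pairs, so no block entered the main comparisons. With group means removed, 2 of 9 correlations between libraries of the same number exceeded 0.1. With so few libraries this cannot tell whether a shared number marks a shared animal, day or batch. A further sheet that mixes FPKM with scaled values was left out.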

Results

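Gene expression was measured by RNA sequencing in tissue that had grown through conduits bridging a 2 cm gap in the sciatic nerve, the main nerve of the hind limb, of rats at day 14 after implantation. The Hollow conduit is an empty tube. The AFMC conduit has a lumen filled with aligned fibers and lengthwise microchannels. The AFMC-AA-SP conduit is an AFMC conduit that also carries spermidine, a polyamine, on its fibers and L-ascorbic acid (vitamin C) within them. Each of the 3 groups had 3 libraries. Replicates 1, 2 and 3 held 22123294, 18713061 and 22357385 counts in Hollow, 26074134, 18716985 and 20954722 in AFMC, and 20188698, 20851786 and 18314489 in AFMC-AA-SP. AFMC replicate 3 stood apart from the other 8 libraries: its score on the first principal component of log2 CPM, which held 32.9% of the variance, was 72.3, against -23.5 to 9.93. Interleukin 1 beta (Il1b), a cytokine of acute inflammation, was at 560 CPM in that library and at 45.8 and 73.6 CPM in AFMC replicates 1 and 2. Jchain, which joins antibody units in plasma cells, was at 938 CPM there and at 33.0 and 108 CPM in the other AFMC replicates. Libraries also differed in how much they drew from long genes. Across genes, which are not independent replicates, Spearman's rho between gene length and a library's deviation from the mean was -0.307, -0.0344 and -0.191 in AFMC, 0.248, 0.0830 and 0.0140 in Hollow, and 0.184, 0.162 and 0.0447 in AFMC-AA-SP.

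The comparison of AFMC with Hollow addresses what the internal guidance structure changes. Schwann cell genes, which mark the glia that ensheathe peripheral axons, were lower as a group in AFMC, with 18 of 18 tested members negative, a median log2 fold change of -0.55 and a score difference of -0.62 ± 0.19 (SE, n = 3 per group). Pro-inflammatory cytokine, chemokine and enzyme genes were higher as a group, with 26 of 26 members positive, a median of 1.22 and a score difference of 1.10 ± 0.50 (SE, n = 3 per group). Camera's adjusted p at the preset correlation was 6.32e-13 for the Schwann cell list and 1.56e-12 for the inflammatory list, and each had an adjusted p = 0.530 with an estimated correlation. Without AFMC replicate 3 the medians were -0.45 and 0.46, and both lists were still called at the preset correlation. No single gene passed edgeR's threshold, so the values of genes below are values and not calls.

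Among nerve genes, 12 of the 18 Schwann cell members had an unadjusted edgeR p under 0.05, all lower, and 9 passed when adjusted over the list alone, against 0 over all genes tested. Scn7a, a sodium channel of Schwann cells, was at 53.2 ± 7.60 CPM (SD, n = 3) in AFMC and 101 ± 7.48 CPM in Hollow, a log2 fold change of -0.93 ± 0.11 (SE; adjusted p = 0.102 by edgeR, 3.13e-09 by DESeq2). Cdh19, a cadherin of the Schwann lineage, had -0.96 ± 0.19, and Sox10, the lineage's transcription factor, had -0.56 ± 0.13 (SE; adjusted p = 0.103 and 0.115 by edgeR). The list of the repair state, which Schwann cells enter when they lose their axon, was called lower with 18 of 19 members negative and a median of -0.56. In it Sox2, a transcription factor of immature and repair Schwann cells, had -0.70 ± 0.12, Bdnf, a neurotrophin, -0.80 ± 0.15 and Ngfr, the low-affinity neurotrophin receptor, -0.56 ± 0.11 (SE). Gap43, a growth cone protein also made by denervated Schwann cells, had -0.71 ± 0.23, and Jun, which drives the repair state, -0.12 ± 0.08 (SE). The myelin list was called lower with 19 of 19 members negative and a median of -0.55, which was -0.29 without Hollow replicate 2. Of its members, Cnp, an enzyme of myelinating glia, had -0.35 ± 0.08 and myelin basic protein Mbp -0.54 ± 0.21 (SE). The repair and myelin lists each had an adjusted p = 0.530 with an estimated correlation. The genes of the Schwann cell list are long, with a median length of 3862.5 bp against 2956 bp for all tested genes, and with an offset that follows gene length, chosen after seeing the data, the list's median was -0.55.

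Basement membrane genes went the same way as a group. The list of laminins, type IV collagens and their integrins was called lower with 20 of 21 members negative and a median of -0.25 (adjusted p = 0.530 with an estimated correlation), which was -0.15 with the length offset. Its members Lama2, a laminin chain of Schwann cells and muscle, and Itga6, a laminin receptor, had -0.53 ± 0.14 and -0.53 ± 0.13 (SE). Axon guidance receptors were called lower, with 23 of 33 members negative and a median of -0.21 (adjusted p = 0.557 with an estimated correlation). That call ended with the length offset, with a median of -0.06 and an adjusted p of 0.110, and without AFMC replicate 1 (median -0.16), and the median was -0.11 without Hollow replicate 1 and -0.12 without AFMC replicate 3. Robo2, the Slit receptor, was at 9.72 ± 2.56 CPM in AFMC and 24.2 ± 4.84 CPM in Hollow (SD, n = 3), a log2 fold change of -1.32 ± 0.21 (SE), and Plxna4, a semaphorin receptor subunit, had -0.80 ± 0.19. Outside the lists, the genes of smallest p on the lower side were Ptpn4, a tyrosine phosphatase, at -1.08 ± 0.13, and Zfp536, a zinc finger protein, at -1.46 ± 0.19 (SE; adjusted p = 0.102 each by edgeR).

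Immune lists were called higher in AFMC, and apart from the interferon list they stood highest in AFMC replicate 3. The neutrophil list had a median of 2.58 (13 of 15 positive), the T and NK cell list 1.01 (21 of 22), the list of MHC class II antigen presentation 0.79 (16 of 17) and the macrophage list 0.36 (20 of 23), each with an adjusted p = 0.530 with an estimated correlation. Without AFMC replicate 3 these medians were 1.08, 0.17, 0.28 and 0.33, and all 4 were still called. The macrophage median was 0.24 without Hollow replicate 1. The neutrophil members of smallest p, Padi4 and Camp, lay near the floor in all 9 libraries. They were at most 0.222 and 0.374 CPM in Hollow, and at most 2.83 and 3.73 CPM in AFMC, both in replicate 3. Mpo, another neutrophil gene near the floor, went the other way, at 1.51, 1.34 and 1.27 CPM in Hollow and 0.198, 0.865 and 0.248 CPM in AFMC. Ccl3, a chemokine for monocytes, was at 77.0 ± 43.2 CPM (SD, n = 3) in AFMC and 24.5 ± 2.69 CPM in Hollow, with a log2 fold change of 1.65 ± 0.33, and Cxcl3, a neutrophil attractant, had 1.53 ± 0.30 (SE). Il1b had 3.31 ± 0.84 with all libraries and 1.39 without AFMC replicate 3. Cd2 and Cd8b of T cells had 1.37 ± 0.27 and 0.83 ± 0.19, Ccr7, which guides dendritic cells and lymphocytes, 1.35 ± 0.25, and RT1-DMb, which loads peptides on MHC class II, 0.68 ± 0.11 (SE). Cd14 and Fcer1g of macrophages had 0.85 ± 0.23 and 0.63 ± 0.15, while the general macrophage marker Cd68 had 0.36 ± 0.20, Arg1 0.67 ± 0.26 and Mrc1, of alternatively activated macrophages, -0.12 ± 0.16 (SE). Pf4, a platelet and macrophage chemokine, had 0.88 ± 0.14 (SE; adjusted p = 0.102 by edgeR). The B and plasma cell list (median 1.67) and the interferon list (0.57) lost their calls without AFMC replicate 3, at medians of 0.17 and 0.30, and had adjusted p = 0.590 and 0.679 with an estimated correlation. The interferon call also ended without Hollow replicate 2 (median 0.37), and its median was 0.89 without Hollow replicate 3 and 0.87 without AFMC replicate 2.

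Among the other lists, adipocyte genes were called lower in AFMC with 13 of 14 members negative and a median of -0.81 (adjusted p = 0.530 with an estimated correlation), which was -0.52 without AFMC replicate 3. Adipoq, a fat cell hormone, had -1.40 ± 0.29 and Plin1, the coat of lipid droplets, -1.49 ± 0.37 (SE). The polyamine list was called higher with 17 of 22 members positive and a median of 0.18 (adjusted p = 0.530 with an estimated correlation). Its call ended with the length offset (median 0.10, adjusted p = 0.0871) and without AFMC replicate 1 (median 0.13). Smox, which oxidizes spermine to spermidine, was at 71.2 ± 6.82 CPM in AFMC and 45.9 ± 1.32 CPM in Hollow (SD, n = 3), a log2 fold change of 0.63 ± 0.08 (SE; adjusted p = 0.102 by edgeR, 4.23e-07 by DESeq2). Atp13a2, a lysosomal polyamine exporter, had 0.91 ± 0.22, and the ornithine decarboxylase Odc1 and the acetyltransferase Sat1 each had 0.18, with SEs of 0.15 and 0.11. The cell division list was called lower (median -0.17, adjusted p = 0.679 with an estimated correlation) and lost its call without Hollow replicate 2 (-0.04), and its median was -0.29 without Hollow replicate 3. The cholesterol synthesis list was called lower (median -0.20, adjusted p = 0.715 with an estimated correlation) and lost its call without Hollow replicate 2 (-0.07), AFMC replicate 2 (-0.13) or AFMC replicate 3 (-0.12), and its median was -0.32 without AFMC replicate 1. The skeletal muscle list was called higher at 0.50 (adjusted p = 0.715 with an estimated correlation), with a score difference of 1.02 ± 1.38 (SE, n = 3 per group). It lost its call without Hollow replicate 2 (0.11), Hollow replicate 3 (0.09) or AFMC replicate 1 (-0.42), and its median was 2.79 without Hollow replicate 1 and 0.96 without AFMC replicate 2. The muscle actin Acta1 was at 324 ± 301 CPM in AFMC and 217 ± 317 CPM in Hollow (SD, n = 3).

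In the study's own sheets, chosen by the study on these samples and so no independent evidence, the Schwann cell transdifferentiation genes were lower in AFMC, with 11 of 11 negative, a median of -0.56 and 6 passing when adjusted over the list alone. The axon regeneration genes had a median of -0.33 with 12 of 14 negative, the guidance receptors -0.22 with 16 of 23, the proliferation genes -0.26 with 4 of 5, and the phagocytosis receptors -0.10 with 9 of 11. All 5 sheets were called by camera at the preset correlation and none with an estimated one, where the adjusted p was 0.104 for 4 of them and 0.186 for the phagocytosis receptors. Fry, adjusted over the 5 sheets, called all 5, with adjusted p from 0.00604 to 0.0351. Chl1, a cell adhesion molecule of axons and Schwann cells, had -1.01 ± 0.18, Map1b, a microtubule protein of growing axons, -0.95 ± 0.23, Nf1, a brake on Ras signalling, -0.73 ± 0.14 and Megf10, an engulfment receptor, -0.54 ± 0.12 (SE). The sheet for migration held only Nf1.

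Across all genes, edgeR called 0 higher and 0 lower in AFMC than in Hollow, with a smallest adjusted p of 0.102. At an unadjusted p under 0.05, 1316 were higher and 1739 lower, where 783 in all are expected by chance. DESeq2 called 414 higher and 614 lower. Without AFMC replicate 2, edgeR called 217 higher and 677 lower, and without AFMC replicate 1 it called 4 and 1. In 3526 genes (22.5%) the groups did not overlap, where chance gives 10% for 3 against 3 libraries. Of the 40 lists, 17 were called, 9 higher and 8 lower, and 10 of the 17 kept their call whichever library was left out. No list was called with an estimated correlation, in this comparison or the others, and fry called none of the 40. No annotation term was enriched among edgeR's calls, as there were none, and 71 were among those of DESeq2.

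**Figure D1:**
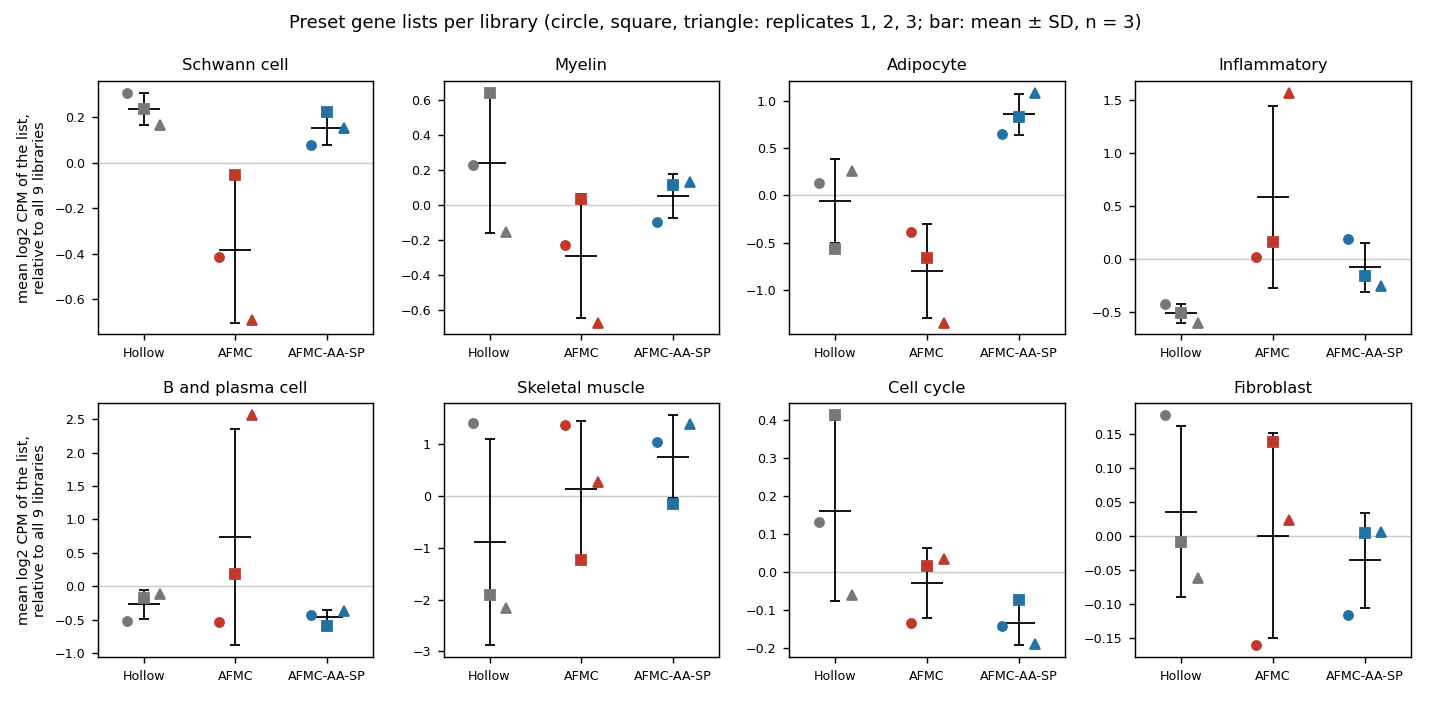
Score of 8 gene lists in each library, as mean log2 CPM relative to all 9 libraries, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). AFMC replicate 3 has the highest inflammatory score (1.57) and the lowest Schwann cell score (-0.69), and the adipocyte scores of AFMC-AA-SP (0.65, 0.83 and 1.09) lie above those of the other groups.

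The comparison of AFMC-AA-SP with AFMC addresses what the added spermidine and ascorbic acid change. Adipocyte genes were higher as a group in AFMC-AA-SP, with 13 of 14 members positive, a median log2 fold change of 2.17 and a score difference of 1.66 ± 0.31 (SE, n = 3 per group). Schwann cell genes were also higher as a group, with 17 of 18 positive, a median of 0.49 and a score difference of 0.54 ± 0.19 (SE, n = 3 per group). Inflammatory genes were lower as a group, with 25 of 26 negative, a median of -0.82 and a score difference of -0.66 ± 0.51 (SE, n = 3 per group). Camera's adjusted p at the preset correlation was 5.16e-21, 4.00e-11 and 1.44e-06 for these lists, and with an estimated correlation their adjusted p were 0.223, 0.522 and 0.719. Without AFMC replicate 3 the medians were 1.75, 0.35 and -0.10, and all 3 lists were still called at the preset correlation. With the length offset and without AFMC replicate 3 together, the adipocyte and Schwann cell lists were called at 1.77 and 0.29, and the inflammatory list was not, at -0.09 (adjusted p = 0.217).

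In the adipocyte list, 11 of the 14 members passed when adjusted over the list alone, all higher, against 0 over all genes tested. Adipoq was at 39.3 ± 9.29 CPM (SD, n = 3) in AFMC-AA-SP and 6.98 ± 2.86 CPM in AFMC, a log2 fold change of 2.48 ± 0.29 (SE; adjusted p = 0.0553 by edgeR, 1.98e-13 by DESeq2). Plin1 had 2.57 ± 0.38 (SE; adjusted p = 0.0860 by edgeR, 4.51e-09 by DESeq2). Skeletal muscle genes, another tissue around the nerve, were not called, with a median of 0.29 and a score difference of 0.63 ± 0.89 (SE, n = 3 per group). The red blood cell list was called higher at 0.89 (adjusted p = 0.737 with an estimated correlation) and lost its call without AFMC replicate 2 (0.75) or AFMC-AA-SP replicate 2 (0.25), where Slc4a1 had 1.72 ± 0.64 and Alas2 1.07 ± 0.53 with all libraries (SE). Slc4a1 was at 2.52, 6.69 and 0.986 CPM in AFMC-AA-SP and near the floor in AFMC, at 0.830, 1.08 and 1.19 CPM.

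Of the Schwann cell list, 8 members passed when adjusted over the list alone, all higher. Scn7a was at 108 ± 6.29 CPM in AFMC-AA-SP and 53.2 ± 7.60 CPM in AFMC (SD, n = 3), a log2 fold change of 1.02 ± 0.11 (SE; adjusted p = 0.0553 by edgeR, 5.99e-12 by DESeq2). Ngfr had 0.60 ± 0.11, Sox10 0.46 ± 0.13 and, in the repair list, Sox2 0.78 ± 0.12 and Jun 0.27 ± 0.08 (SE). The repair list was called higher with 16 of 19 members positive and a median of 0.33 (adjusted p = 0.719 with an estimated correlation). The myelin list was called higher with 19 of 19 positive and a median of 0.26 (adjusted p = 0.737 with an estimated correlation), but lost its call without AFMC replicate 3 (0.09), and its median was 0.48 without AFMC replicate 2. Its members Drp2, a dystrophin-related protein of the Schwann cell surface, and Mbp had 0.68 ± 0.25 and 0.21 ± 0.21 (SE). With the length offset the Schwann cell, repair and myelin medians were 0.44, 0.30 and 0.32.

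Receptors of neurotrophic factors were called higher with 13 of 16 members positive and a median of 0.15 (adjusted p = 0.621 with an estimated correlation), which was 0.09 without AFMC replicate 1 and 0.26 without AFMC replicate 3. Ntrk2, the BDNF receptor, was at 21.5 ± 2.90 CPM in AFMC-AA-SP and 11.1 ± 2.04 CPM in AFMC (SD, n = 3), a log2 fold change of 0.95 ± 0.15 (SE; adjusted p = 0.0864 by edgeR). Robo2 had 1.04 ± 0.21 and Nrp1, a receptor for semaphorins and VEGF, 0.48 ± 0.14 (SE). The guidance receptor list, called higher at 0.25 (adjusted p = 0.719 with an estimated correlation), lost its call with the length offset (0.09), without AFMC replicate 1 (0.14) and without AFMC replicate 3 (0.17). The basement membrane list was called higher at 0.19 with 18 of 21 positive (adjusted p = 0.719 with an estimated correlation), with Itga7 at 0.48 ± 0.12 and Lama2 at 0.47 ± 0.14 (SE). Its call ended with the length offset (median 0.06, adjusted p = 0.231), and its median was 0.12 without AFMC replicate 3. The perineurial list was called higher at 0.24 (adjusted p = 0.628 with an estimated correlation), with Tenm2, a teneurin, at 0.94 ± 0.18 (SE). It lost its call without AFMC replicate 3 (0.19), and its median was 0.38 without AFMC replicate 2. The neurotrophic factor list was called higher at 0.26 (adjusted p = 0.628 with an estimated correlation), with Hgf at 0.60 ± 0.19 and Cdnf at 0.81 ± 0.26 (SE), and lost its call without Hollow replicate 1 (0.26), AFMC replicate 1 (0.20), AFMC replicate 3 (0.25) or AFMC-AA-SP replicate 2 (0.16). Its median was 0.40 without AFMC replicate 2 and 0.39 without AFMC-AA-SP replicate 1. Cdnf was near the floor, at 1.45, 1.40 and 1.21 CPM in AFMC-AA-SP and 0.948, 0.757 and 0.596 CPM in AFMC.

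Immune lists were called lower in AFMC-AA-SP than in AFMC, and most of these calls rested on AFMC replicate 3. The B and plasma cell list had a median of -2.12, the T and NK cell list -0.74, the neutrophil list -1.29 and the MHC class II list -0.39, with adjusted p = 0.719, 0.737, 0.759 and 0.719 with an estimated correlation. Without AFMC replicate 3 these medians were -0.14, 0.05, 0.14 and -0.00, and none of the 4 lists was called. The neutrophil call also ended without AFMC-AA-SP replicate 2 (-1.11) or 3 (-0.97) and with the length offset (-1.16), and the MHC class II median was -0.61 without AFMC replicate 1. Mpo, a neutrophil gene near the floor, went against its list, at 1.98, 2.62 and 1.48 CPM in AFMC-AA-SP and 0.198, 0.865 and 0.248 CPM in AFMC. The macrophage list was called lower with 21 of 23 members negative and a median of -0.23 (adjusted p = 0.719 with an estimated correlation), which was -0.13 without AFMC replicate 3, -0.15 without AFMC-AA-SP replicate 2 and -0.13 with the length offset. With the offset and without AFMC replicate 3 together it was -0.06 and not called (adjusted p = 0.129). Ccl3 had -1.30 ± 0.33, Ccl7, a monocyte attractant, -0.48 ± 0.15 and Cd14 -0.74 ± 0.23 (SE). Il1b had -2.10 ± 0.80 with all libraries and -0.18 without AFMC replicate 3, and Jchain had -3.81 ± 1.04 and -1.46 (SE). Cd68, Arg1 and Mrc1 had -0.13 ± 0.20, -0.09 ± 0.26 and 0.19 ± 0.16 (SE). The mast cell list was called higher at 0.42 (adjusted p = 0.719 with an estimated correlation), with Kit, the stem cell factor receptor, at 0.51 ± 0.20 and Cpa3 at 0.61 ± 0.31 (SE), and lost its call without Hollow replicate 1 (0.37), AFMC replicate 2 (0.49) or 3 (0.25), or AFMC-AA-SP replicate 1 (0.30) or 3 (0.40).

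Genes of the pathways of the added compounds were read as well. The polyamine list was called lower in AFMC-AA-SP with 19 of 22 members negative and a median of -0.18 (adjusted p = 0.628 with an estimated correlation). Its call ended with the length offset (median -0.12, adjusted p = 0.114), without AFMC replicate 1 (-0.19) and without AFMC-AA-SP replicate 2 (-0.16). Smox was at 52.3 ± 3.07 CPM in AFMC-AA-SP against 71.2 ± 6.82 CPM in AFMC (SD, n = 3), a log2 fold change of -0.45 ± 0.08 (SE; adjusted p = 0.104 by edgeR, 0.00109 by DESeq2). Slc22a3, an organic cation transporter that carries polyamines, had 2.10 ± 0.42, from 0.600 to 2.58 CPM, and Odc1 and Sat1 had -0.32 ± 0.15 and -0.01 ± 0.11 (SE). The list of ascorbate transport and ascorbate-dependent hydroxylation was not called, with 8 of 21 members positive and a median of -0.11 (adjusted p = 0.605 at the preset correlation). Slc23a2, the main ascorbate transporter, had 0.22 ± 0.09 and P4ha1, a prolyl hydroxylase of collagen, 0.00 ± 0.16 (SE). The antioxidant list was called lower at -0.15 (adjusted p = 0.737 with an estimated correlation), with the ferritin heavy chain Fth1 at -0.64 ± 0.18 and Sod2 at -0.93 ± 0.34 (SE), and lost its call with the length offset (-0.05) and without AFMC replicate 1 (-0.04) or AFMC-AA-SP replicate 1 (-0.10) or 2 (-0.11). The cell division list was called lower at -0.12 (adjusted p = 0.877 with an estimated correlation) and lost its call without AFMC replicate 2 or 3 or AFMC-AA-SP replicate 3, each at -0.11, or without AFMC-AA-SP replicate 1 (-0.13). On the lower side the other genes of smallest p were Masp1, a protease of the complement system, at -0.64 ± 0.11 and Tmem63a, an ion channel opened by stretch, at -0.39 ± 0.07, and on the higher side Ptpn4 had 1.14 ± 0.13 (SE; adjusted p = 0.0896, 0.107 and 0.0553 by edgeR).

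In the study's own sheets, which the study chose on these samples, the axon regeneration genes were higher in AFMC-AA-SP with 14 of 14 positive and a median of 0.28. The transdifferentiation genes had a median of 0.46 with 10 of 11 positive, the phagocytosis receptors 0.23 with 11 of 11 and the guidance receptors 0.17 with 15 of 23. These 4 sheets were called by camera at the preset correlation, and with an estimated correlation their adjusted p were 0.113, 0.113, 0.136 and 0.208. The proliferation genes were not called by camera, with a median of 0.03. Fry called the transdifferentiation, axon regeneration, phagocytosis and proliferation sheets, with adjusted p of 0.0144, 0.0176, 0.0193 and 0.0261, and not the guidance receptors (0.0706). Chl1 had 1.10 ± 0.18, Nf1 0.68 ± 0.14 and Apod, a lipid carrier of regenerating nerve, 0.47 ± 0.12 (SE).

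Across all genes, edgeR called 0 higher and 0 lower in AFMC-AA-SP than in AFMC, with a smallest adjusted p of 0.0553. At an unadjusted p under 0.05, 1579 were higher and 1129 lower, where 783 in all are expected by chance. DESeq2 called 466 higher and 128 lower. Without AFMC replicate 2, edgeR called 506 higher and 73 lower, without AFMC replicate 1 it called 2 and 2, and without AFMC replicate 3 it called Adipoq and Scn7a higher and Rpl35al1, a ribosomal protein gene copy, lower. In 3576 genes (22.8%) the groups did not overlap, where chance gives 10%. Of the 40 lists, 20 were called, 11 higher and 9 lower, and 7 of the 20 kept their call whichever library was left out, while 10 lost it without AFMC replicate 3. No annotation term was enriched among edgeR's calls, as there were none, and 4 were among those of DESeq2.

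**Figure D2:**
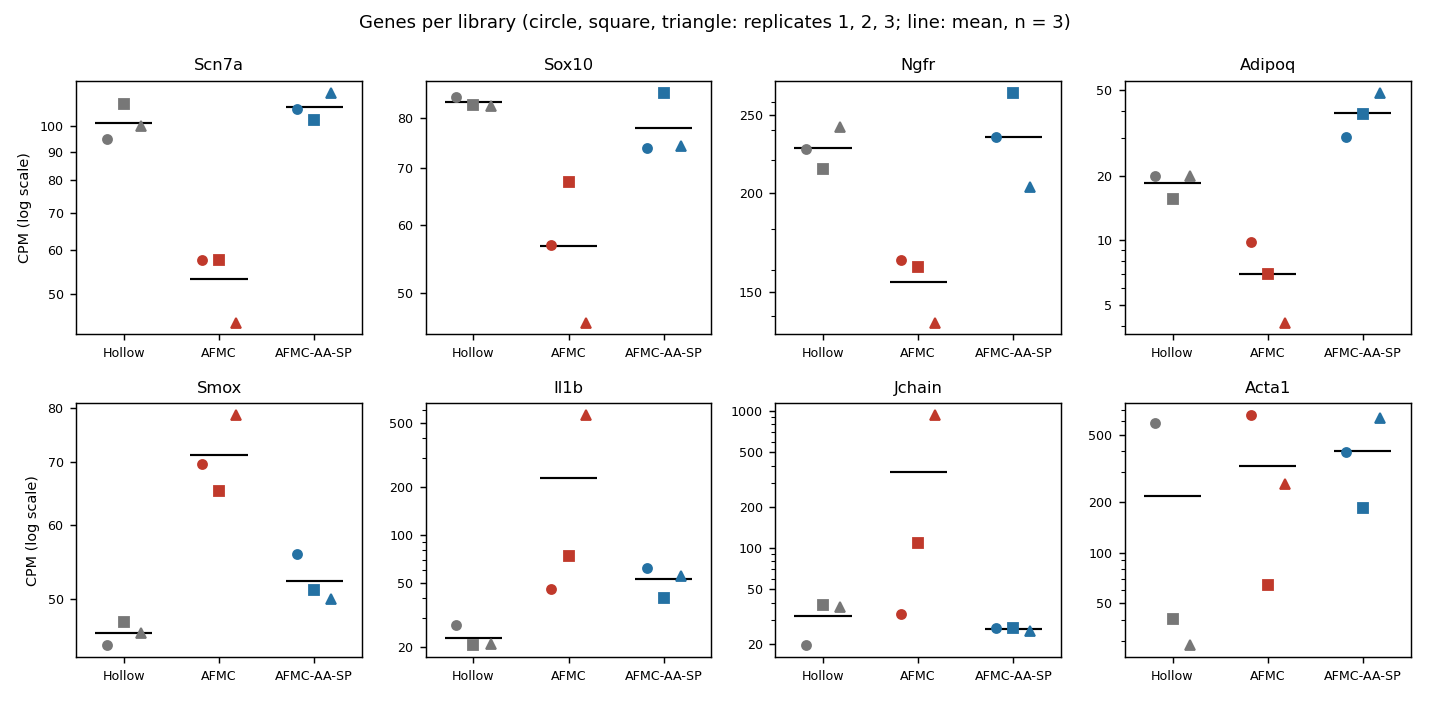
CPM of 8 genes in each library on a log axis, with circles, squares and triangles for replicates 1, 2 and 3 and a line for the mean (n = 3). Scn7a and Adipoq are lower and Smox higher in all 3 AFMC libraries than in all 6 others, while Il1b and Jchain are far higher in AFMC replicate 3 (560 and 938 CPM) than in any other library. The rule that picked Scn7a and Smox asks for no overlap between the groups compared, so their separation follows from that choice.

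The comparison of AFMC-AA-SP with Hollow sets both changes to the conduit against the empty tube. Adipocyte genes were higher as a group in AFMC-AA-SP, with 13 of 14 positive, a median log2 fold change of 1.0 and a score difference of 0.91 ± 0.29 (SE, n = 3 per group). Cell division genes were lower as a group, with 25 of 26 negative, a median of -0.33 and a score difference of -0.30 ± 0.14 (SE, n = 3 per group). Camera's adjusted p at the preset correlation was 5.73e-18 and 3.30e-20, and the adjusted p with an estimated correlation were 0.328 and 0.547. The cell division median was -0.19 without Hollow replicate 2. The Schwann cell list was not called, with 11 of 18 negative and a median of -0.09 (adjusted p = 0.140 at the preset correlation), and Scn7a, Sox10 and Ngfr had group means of 108, 77.9 and 235 CPM against 101, 83.5 and 227 CPM in Hollow.

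Adipoq had 1.08 ± 0.28 and Lep, the fat hormone leptin, 1.88 ± 0.52, while Tpx2, of the mitotic spindle, had -0.39 ± 0.11 and Cdk1, the kinase that starts mitosis, -0.38 ± 0.12 (SE). Antigen presentation by MHC class II was called higher at 0.35 with 16 of 17 positive and the neutrophil list at 1.06 with 14 of 15 (adjusted p = 0.547 each with an estimated correlation). The 2 neutrophil members of smallest p lay near the floor and went opposite ways. Retnlg had 1.23 ± 0.51 (SE), at 3.68, 4.59 and 2.96 CPM in AFMC-AA-SP and 2.49, 1.60 and 0.703 CPM in Hollow. Ltf was lower, at 0.242, 0.234 and 0.0548 CPM in AFMC-AA-SP and 0.534, 0.588 and 0.747 CPM in Hollow. The inflammatory list was called higher at 0.34 with 22 of 26 positive (adjusted p = 0.683 with an estimated correlation), which was 0.13 without AFMC-AA-SP replicate 1. Cholesterol synthesis was called lower at -0.20 with 20 of 22 negative (adjusted p = 0.683 with an estimated correlation), which was -0.09 without Hollow replicate 2. The skeletal muscle list was called higher at 0.88 with 17 of 18 positive and a score difference of 1.65 ± 1.24 (SE, n = 3 per group; adjusted p = 0.683 with an estimated correlation). Its median was 3.29 without Hollow replicate 1, 0.43 without Hollow replicate 2, 0.41 without Hollow replicate 3 and 0.52 without AFMC-AA-SP replicate 3. Among the genes of smallest p were the catalase gene Cat at 0.41 ± 0.08 and the complement gene C4b at 0.67 ± 0.14 on the higher side (SE). On the lower side they were Hnrnpa3, an RNA-binding protein, at -0.55 ± 0.09, Shcbp1, which acts in cell division, at -0.49 ± 0.11, and Stc2, a secreted glycoprotein, at -1.0 ± 0.24 (SE; adjusted p by edgeR from 0.764 upward). Mertk, an engulfment receptor, and Apoe, a lipid carrier, had 0.43 ± 0.16 and 0.50 ± 0.19 (SE).

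The other 14 lists called in this comparison lost their call when 1 library was left out, and their adjusted p with an estimated correlation ran from 0.547 to 0.736. Called higher were the interferon list at 0.73 (-0.06 without AFMC-AA-SP replicate 1, 0.45 without Hollow replicate 2), the T and NK cell list at 0.24 (0.14 without AFMC-AA-SP replicate 1, 0.16 and 0.36 without Hollow replicates 2 and 3) and the muscle progenitor list at 0.76. The last was not called without Hollow replicate 2 (0.31) or 3 (0.44), AFMC replicate 3 (0.76) or AFMC-AA-SP replicate 1 (0.55) or 3 (0.34), and was 2.21 without Hollow replicate 1 and 1.28 without AFMC-AA-SP replicate 2. The macrophage list at 0.15 was not called without Hollow replicate 1 (0.03) or AFMC-AA-SP replicate 1 (0.05) or 3 (0.14), and was 0.25 without Hollow replicate 2 and 0.23 without AFMC-AA-SP replicate 2. The phagocytosis list at 0.13 was not called without Hollow replicate 1 (0.11) or 2 (0.09) or AFMC-AA-SP replicate 3 (0.09), and was 0.24 without Hollow replicate 3 and 0.21 without AFMC-AA-SP replicate 2. The red blood cell list at 0.44 was called only with all libraries or without Hollow replicate 1 (0.71) or AFMC-AA-SP replicate 3 (0.81), ended with the length offset (0.45), and was -0.22 without AFMC-AA-SP replicate 2 and 0.33 to 0.59 without each of the other 6.

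Called lower were the myelin list at -0.18 with 19 of 19 negative, which was not called without Hollow replicate 2 (-0.01) and was -0.40 without Hollow replicate 3, and the repair list at -0.17, not called without Hollow replicate 1 (-0.07) or AFMC-AA-SP replicate 1 (-0.08) or 3 (-0.07). The ascorbate list at -0.10 was not called without Hollow replicate 2 (-0.05) or AFMC-AA-SP replicate 1 (-0.07), and its members P4ha2 and Plod2, hydroxylases of collagen, had -0.40 ± 0.13 and -0.46 ± 0.20 (SE). The hypoxia and glycolysis list at -0.16 was not called without Hollow replicate 2 (0.05) or AFMC-AA-SP replicate 3 (-0.13), and was -0.27 without Hollow replicate 1. The fibrosis list at -0.11 was not called without Hollow replicate 1 (-0.08) or AFMC-AA-SP replicate 1 (-0.02), and was -0.19 and -0.21 without AFMC-AA-SP replicates 2 and 3. The mural cell list at -0.13 was not called without Hollow replicate 1 (0.02) or 3 (-0.13) or AFMC-AA-SP replicate 1 (0.00) or 2 (-0.10), and its member Cspg4, the pericyte proteoglycan NG2, had -0.67 ± 0.17 (SE). The basement membrane list at -0.05 was not called without Hollow replicate 1 (-0.03) or AFMC-AA-SP replicate 1 (-0.02), and was -0.12 without Hollow replicate 3. The fibroblast list at -0.03 was not called without Hollow replicate 1 (0.03) or AFMC-AA-SP replicate 1 (0.01), and was -0.05, -0.08 and -0.09 without Hollow replicates 2 and 3 and AFMC-AA-SP replicate 2.

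Across all genes, edgeR called 0 higher and 0 lower in AFMC-AA-SP than in Hollow, with a smallest adjusted p of 0.108. At an unadjusted p under 0.05, 265 were higher and 242 lower, where 783 in all are expected by chance. All 9 libraries share the estimate of spread, and without AFMC replicate 3, which is outside this comparison, 434 were higher and 331 lower. DESeq2 called 7 higher, among them Cat, C4b and Pf4, and 1 lower, Hnrnpa3. In 1568 genes (10%) the groups did not overlap, the share that chance gives. Of the 40 lists, 21 were called, 11 higher and 10 lower, and 11 of them lost their call without AFMC-AA-SP replicate 1. No annotation term was enriched, by edgeR's calls or those of DESeq2, and none of the study's sheets was called by camera or by fry, whose smallest adjusted p were 0.224 and 0.544.

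The comparisons were also set against each other across genes. The log2 fold changes of AFMC against Hollow and of AFMC-AA-SP against AFMC had a Pearson r of -0.77 across the 15659 tested genes, which are not independent replicates. Both comparisons contain the AFMC libraries, with opposite sign, so a negative r arises without any effect. The spreads measured within the groups, largest in AFMC, would alone give an r of -0.64. With each library left out in turn, r ran from -0.82 to -0.64, where the spreads of the same libraries would give -0.77 to -0.57. The gap was smallest without AFMC replicate 3, with an r of -0.66 against -0.66, and without Hollow replicate 1, with -0.64 against -0.63, and largest without Hollow replicate 2, with -0.76 against -0.57. In 100 simulated sets of unchanged libraries, which give every group the same spread, r was from -0.56 to -0.44. The covariance was -0.199, and the spread between the AFMC libraries alone would give -0.0680. The spreads were taken on log2 CPM, which damps genes of low counts more than the fitted fold changes do. These values are therefore not parts of a whole, and an r from the spreads is approximate. The comparisons had no edgeR call in common, as there were none, while DESeq2 called 409 genes in both, all in opposite directions, which the AFMC libraries they have in common favour. For AFMC against Hollow and AFMC-AA-SP against Hollow, which contain the same Hollow libraries, r was 0.31. The measured spreads gave 0.47 and the simulated sets 0.45 to 0.56. Without Hollow replicate 1, r was 0.49, where the spreads would give 0.51. The covariance was 0.0546, and the spread of Hollow, with the same limit, would give 0.0433. DESeq2 called 4 genes in both, all in the same direction.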

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

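The length offset, the length offset without AFMC replicate 3 and the limma weights per library were chosen after seeing the data. The other alternatives in this section were fixed before the data were examined. Over all alternatives, the medians of the called lists kept their sign and call in 955 cases, kept their sign and lost the call in 245, and changed sign in 13. Of the lost calls, 58 each came from the estimated correlation and fry, which leave the medians unchanged. The limma weights gave 13, log2(FPKM + 1) 8, the 2 groups alone 5, and the block and the 1 CPM filter 3 each. The values of the named genes, none called by edgeR with all libraries, kept their sign uncalled in 4167 cases, kept it and were called in 129, and changed sign uncalled in 47. Of the 4167, 199 came from the minimum fold change, which reuses the main fit and could not add a call. Leaving out a library outside a comparison also counts in these tallies. Lists that changed sign when 1 library was left out had medians, over the libraries left out, of -0.42 to 2.79 (skeletal muscle, AFMC against Hollow), -1.53 to 0.14 and -1.06 to 0.048 (neutrophil, and T and NK cell, AFMC-AA-SP against AFMC). For AFMC-AA-SP against Hollow they were -0.090 to 0.031 (fibroblast), -0.15 to 0.018 (mural cell), -0.22 to 0.81 (red blood cell), -0.057 to 1.08 (interferon) and -0.27 to 0.048 (hypoxia and glycolysis). With the length offset without AFMC replicate 3, the neutrophil, T and NK cell and MHC class II lists of AFMC-AA-SP against AFMC changed sign, to 0.13, 0.081 and 0.0066, uncalled. With DESeq2, AFMC had 414 genes higher and 614 lower than Hollow with 71 terms, AFMC-AA-SP had 466 higher and 128 lower than AFMC with 4 terms, and 7 higher and 1 lower than Hollow, and 409 and 4 genes were shared by the pairs of comparisons, against 0 with edgeR in each case. Leaving out 1 library in turn gave 0 to 217 genes higher, 0 to 677 lower, 15 to 21 lists and 0 to 61 terms for AFMC against Hollow. It gave 0 to 506 higher, 0 to 73 lower, 11 to 20 lists and 0 to 4 terms for AFMC-AA-SP against AFMC, and 0 to 1 higher, 0 to 0 lower and 11 to 20 lists for AFMC-AA-SP against Hollow. Shared genes ran from 0 to 484 for the comparisons that hold AFMC and from 0 to 0 for those that hold Hollow. The highest counts of genes came without AFMC replicate 2, where 617 genes of AFMC against Hollow and 376 of AFMC-AA-SP against AFMC were also called by DESeq2. Camera with an estimated correlation and fry called 0 lists in each comparison, against 17, 20 and 21. With the replicate number as a block, 1 gene was higher in AFMC than in Hollow (the unnamed ENSRNOG00000065191), 2 were lower in AFMC-AA-SP than in AFMC (that gene and Mmp13, a collagenase), and 1 was shared. With no filter on low counts, 6 genes were higher in AFMC-AA-SP than in AFMC: Cdo1, Adipoq, Ptpn4, Itgb8, Tmem179 and Scn7a. With the length offset without AFMC replicate 3, 1 gene was higher (Adipoq), 1 lower (Rpl35al1) and 7 lists were called in that comparison, where 6 of the 20 kept their call and 14 lost it, and 1 gene was higher than in Hollow (ENSRNOG00000070878). That gene was also the 1 called higher than in Hollow by limma on log2(FPKM + 1) for AFMC-AA-SP, and on log2(FPKM + 0.1) for AFMC-AA-SP and for AFMC. The genes listed here were chosen after their values were seen, and the cause was not tested.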

Other observations

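The tests of annotation terms with camera, of gene length by an offset, of AFMC replicate 3, alone and together with gene length, of muscle and fat together and of dilution by immune cells were chosen after the results were seen, as were the genes listed per library, while for the Schwann cell list the bound on gene length, and for all comparisons the test of other splits of the libraries, were written before their own results were seen. Chemokine genes, as the annotation term chemokine activity (12 genes), were higher in AFMC than in Hollow, with a median log2 fold change of 0.71, and lower in AFMC-AA-SP than in AFMC, with -0.63 (camera adjusted p = 9.96e-05 and 0.000468, and 0.995 and 0.944 with an estimated correlation). Without AFMC replicate 3 these medians were 0.53 and -0.51, and both were still called at the preset correlation (adjusted p = 9.12e-05 and 0.00904). Genes of mitotic sister chromatid segregation (24 genes) were lower in AFMC-AA-SP than in Hollow, with a median of -0.31 (adjusted p = 6.63e-09, and 1.0 with an estimated correlation), which was -0.18 without Hollow replicate 2. Ribosome genes (140 genes, median length 1125 bp) were higher in AFMC than in Hollow at 0.13 and lower in AFMC-AA-SP than in AFMC at -0.17. With the length offset these medians were 0.05 and -0.08, and the call against Hollow ended (adjusted p = 0.209), as it did without Hollow replicate 1 (median 0.067, adjusted p = 0.0510). The proteasome (41 genes) and oxidative phosphorylation (117 genes) terms had -0.19 and -0.15 in AFMC-AA-SP against AFMC, and -0.11 and -0.09 with the offset, and the call of oxidative phosphorylation ended without AFMC replicate 1 (median -0.025, adjusted p = 0.286). Of 1946 GO terms, 22 were called higher and 25 lower in AFMC than in Hollow, and 7 and 6 with the offset, 17 and 30 in AFMC-AA-SP against AFMC, and 3 and 5 with it, and 10 and 50 in AFMC-AA-SP against Hollow with or without it. Of 324 KEGG terms, the counts were 57 and 30, and 52 and 6 with the offset, then 42 and 50, and 9 and 34, and then 34 and 18, and 32 and 18. No term of any comparison was called with an estimated correlation.

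The neurofilament genes Nefl and Nefm varied within every group, and which cells their transcripts came from was not tested. Nefl was at 0.622, 23.2 and 7.38 CPM in Hollow replicates 1, 2 and 3, at 8.02, 17.1 and 0.149 CPM in AFMC, and at 9.20, 13.5 and 0.329 CPM in AFMC-AA-SP. Acta1 was at 583, 40.5 and 28.2 CPM, 654, 64.6 and 254 CPM, and 394, 184 and 629 CPM. Ighm, the heavy chain of IgM, was at 135, 860 and 7460 CPM in AFMC. The unnamed protein coding gene ENSRNOG00000070878 (chromosome 5, 110908577 to 110913310) had 0, 1 and 0 counts in Hollow, 24, 20 and 46 in AFMC, and 38, 67 and 55 in AFMC-AA-SP. The unnamed gene ENSRNOG00000065191 (chromosome 6, 136944641 to 136945869) had 14, 2605 and 15584 counts in AFMC, 0, 2 and 0 in Hollow, and 1, 0 and 14 in AFMC-AA-SP.

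The Schwann cell list was lower in AFMC than in both other groups. Gene length bias in the AFMC libraries is argued against as the whole cause, since with the length offset the medians were -0.55 against Hollow and 0.44 for AFMC-AA-SP against AFMC, with score differences of -0.58 ± 0.18 and 0.50 ± 0.18 (SE). Leaving out AFMC replicate 3 gave medians of -0.45 and 0.35 and score differences of -0.47 ± 0.14 and 0.38 ± 0.14 (SE). With the length offset as well, the medians were -0.37 and 0.29 and the score differences -0.44 ± 0.13 and 0.35 ± 0.13 (SE). The rule applied asked for a median and a score difference beyond the bound of 0.2, with the list still called at the preset correlation. The score difference had to pass the bound by more than its SE. Against Hollow, these values argue against that library, alone or with gene length, as the whole cause. For AFMC-AA-SP against AFMC the rule was met by little more than the SE, so the values do not settle it there. Dilution of all resident cells alike by immune cells is argued against by the fibroblast and endothelial lists, whose medians against Hollow lay 0.50 and 0.65 above that of the Schwann cell list, with gaps in score of 0.59 ± 0.17 and 0.65 ± 0.23 (SE). Fewer Schwann cells in AFMC, or less of these transcripts per cell, may explain the pattern as a hypothesis, and neither was tested.

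The inflammatory list was higher in AFMC than in Hollow. Its median was 1.17 with the length offset, 0.46 without AFMC replicate 3 and 0.37 with both, with score differences of 1.05 ± 0.51, 0.61 ± 0.09 and 0.54 ± 0.13 (SE). By the bound of 0.2 these values argue against each as the whole cause, but with so few libraries they cannot exclude it. AFMC replicate 3 carries much of the size. Whether it came from a conduit with more inflammation, with infection or with lymphoid tissue in the sample was not tested. A response to the fibers may add to the pattern as a hypothesis.

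The adipocyte list was higher in AFMC-AA-SP than in AFMC. Its median was 2.19 with the length offset, 1.75 without AFMC replicate 3 and 1.77 with both, with score differences of 1.77 ± 0.34, 1.38 ± 0.19 and 1.47 ± 0.18 (SE), which argues against each as the whole cause. Muscle and fat carried along together at harvest, in a proportion alike in all libraries, is argued against as the whole cause, since with each library's skeletal muscle score as a covariate the adipocyte score difference was 1.61 ± 0.36 (SE, 9 libraries; 1.33 to 1.84 with 1 library left out), and the adipocyte score had a slope of 0.07 ± 0.12 (SE) on the muscle score. Fat taken along without muscle, or with it in a varying proportion, stays open, as may a growth of fat cells within the conduit as a hypothesis. Cfd, an abundant fat cell gene, was at 135, 151 and 167 CPM in AFMC-AA-SP and 106, 108 and 102 CPM in AFMC, and Fabp4, also made by macrophages and endothelium, at 658, 574 and 715 CPM and 941, 517 and 209 CPM.

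Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. As the real splits called 0 genes, every split has as many, so the counts for genes were fixed and decide nothing. The real split of AFMC and Hollow gave 0 genes and 17 lists, where the highest others gave 1 and 24, and 10 and 5 splits gave as many or more, the real one included. For AFMC-AA-SP and AFMC it gave 0 genes and 20 lists, the highest others 1 and 23, and 10 and 3 splits gave as many. For AFMC-AA-SP and Hollow it gave 0 genes and 21 lists, the highest others 3 and 17, and 10 and 1 splits gave as many. At an unadjusted p under 0.05 by edgeR, the real splits had 3055, 2708 and 507 genes and the highest others 1957, 1211 and 713.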
